A study of Mus musculus with 24 samples.

How the data were processed

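Total RNA of the ventral prostate was measured on 24 Affymetrix mouse arrays (MOE430A), 4 biological replicates from each of 6 inbred strains at 8 weeks of age, all wild type and untreated. The deposited table holds 1 intensity per probe set and array on a linear scale. MAS5 is named in the submitters' processing notes, without a version or settings. The deposited intensity columns all had a mean of 143, equal to within 0.00088, so the authors appear in the values to have scaled every array to the same mean. There were 11 values of 0 and no missing values, and no pair of columns was identical. Arrays have no count depth, and their number limits the precision.

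Because the 2% trimmed means of the arrays differed by more than 5% (91.4 to 105), each array was rescaled to a trimmed mean of 98.7. A pseudocount of 16 was added (the mean of the 25th percentiles, rounded) and log2 was taken. Of 22690 probe sets, 64 controls were left out, and 6851 were left out because they did not exceed their array's own 40th percentile on at least 4 arrays, which left 15775. In the platform annotation 20393 probe sets had 1 gene symbol, 691 several and 1606 none, and 20364 of those with 1 symbol matched a RefSeq gene of GRCm38.p6. That table was used for gene names and for the order of the tested genes on the chromosomes. The tested probe sets with 1 symbol covered 9431 genes, and no gene was named from a probe set with several symbols.

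Tests used limma 3.58.1 in R 4.3.3, with 1 coefficient per strain, empirical Bayes moderation (18 residual and 4.85 prior degrees of freedom) and two-sided p values adjusted by Benjamini and Hochberg within each comparison at 0.05. The comparisons were a moderated F test among the 6 strains, each strain against the mean of the other 5, and all 15 pairs. A probe set was strain-distinct when it passed all 5 pairwise tests of a strain in 1 direction and differed from the mean of the other strains by at least 1 on the log2 scale. The genes named for each strain were the 6 with the largest positive and the 6 with the largest negative difference among strain-distinct probe sets with 1 symbol, using the brightest such probe set per gene. For the comparison among all strains they were the 20 with the largest range between strain means. Members of the gene lists are named as examples under their list, and these examples were chosen after their values were seen. They were revised in 5 rounds, in which most examples whose call was lost or turned with an array left out, under another setting or at another probe set were replaced by members whose calls held. The members replaced were Mcm6, Mki67, Mcm5, Pcna, Mcm7 and Nusap1 for AKR, Ifi27l2a, Krt14, Trp63, Col17a1, Des and Myh11 for SWR, Myh11 for 129X1, Des, Fabp4, Car3, Oasl2, Tagln, Acta2, Cnn1 and Smtn for FVB, Hyou1 for BALB/c and Gclc for C57BL/6. The stability of the examples is therefore no evidence about their lists, whose counts cover all measured members.

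The comparisons, the rule for named genes and 42 gene lists were fixed before the data were examined. Lists with at least 5 measured genes were tested with limma's camera on the brightest probe set of each gene, with the preset correlation of 0.01 and adjustment over all lists and strains. Camera with an estimated correlation, fry, and camera on averaged probe sets were alternatives. The score of a list on an array is the mean of its log2 values, each centred on the mean of all 24 arrays. Replicate numbers were not treated as pairs, since the labels do not give any pairing. After the strain means were removed, arrays of different strains with the same number had a mean correlation of 0.0053 over 60 pairs, and 3 of 24 arrays had their best match in another strain at the same number. The 4 highest skeletal muscle scores were however all in arrays numbered 4, so something shared by arrays of a number is not ruled out, and the replicate number in the model was an alternative.

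The workflow was tested on simulated data with 200 changed probe sets per comparison among 15635 to 15676 tested. For a strain against the other 5, it recovered 88.1% to 94% of those changed 2-fold and 52.2% to 74.6% of those changed 1.5-fold, with 4 to 10 unchanged probe sets called. For a pair of strains it recovered 76.1% to 85.1% and 26.9% to 50.7%, with 3 to 10 unchanged called. The F test, on 15663 probe sets, recovered 83.6% and 28.4%, with 10 unchanged called. The strain-distinct rule recovered 37.3% to 44.8% of 2-fold and 92.4% to 98.5% of 4-fold changes. Changes were placed in a single strain and in a far smaller share of probe sets than the real F test called (36.4%). The adjustment of p values depends on that share, so these rates do not carry over directly to the real comparisons. All 6 gene lists shifted by 0.5 were called, as was 1 of 1182 tests of lists that were not shifted. The simulated probe sets were drawn independently of each other, so this rate does not carry over to lists whose genes move together. On the real arrays, random splits gave a median of 17 and up to 34 list calls in 198 tests.

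The alternatives tried were pseudocounts of 1 and 64, no filter, a filter at the 60th percentile, quantile normalization, median centring, trend and robust moderation, array weights, the replicate number in the model, leaving out each array in turn, models restricted to the 8 arrays of a pair or to 2 groups, and the other probe sets of a gene. After the data were examined, the values without rescaling and models with the adipocyte or the smooth muscle score of each array as a covariate were added, as were runs of the gene lists with quantile normalization, the replicate number in the model and each array left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.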

Results

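Gene expression was measured in the ventral prostate of 8-week-old wild-type mice from 6 inbred strains (AKR, SWR, 129X1, FVB, BALB/c and C57BL/6), with 4 biological replicates per strain and 24 arrays in all. According to its title, the series used expression in parental mouse strains to look for genes that modify cancer, so the comparisons asked which transcripts differed among the strains and which set each strain apart. The ventral prostate is a lobe of the mouse prostate whose luminal cells secrete proteins into the seminal fluid. The deposited intensities had the same mean of 143 on every array, and the 2% trimmed means ranged from 91.4 to 105. An array has no count depth, and the number of arrays limits the precision. Values below are log2 of the intensity plus 16 (mean ± SD, n = 4 arrays per strain), and folds are the antilog of log2 differences on that scale, so that folds of faint transcripts are compressed. A probe set is a group of probes for the same transcript, and a gene can have several. The files give no genome build, so no coordinates are reported.

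All 24 arrays had their closest match in an array of the same strain. The correlation between arrays over the 15775 probe sets tested averaged 0.957 within strains (0.939 to 0.975) and 0.925 between strains (0.898 to 0.950). The first 4 principal components carried 15.9%, 11.3%, 10.4% and 9.49% of the variance. Strain accounted for a median of 41.4% of the variance of a probe set, against 21.7% by chance. The 20 brightest probe sets took 5.34% ± 0.31 of the signal in BALB/c and between 3.69% and 4.34% on average in the other strains.

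**Figure D1:**
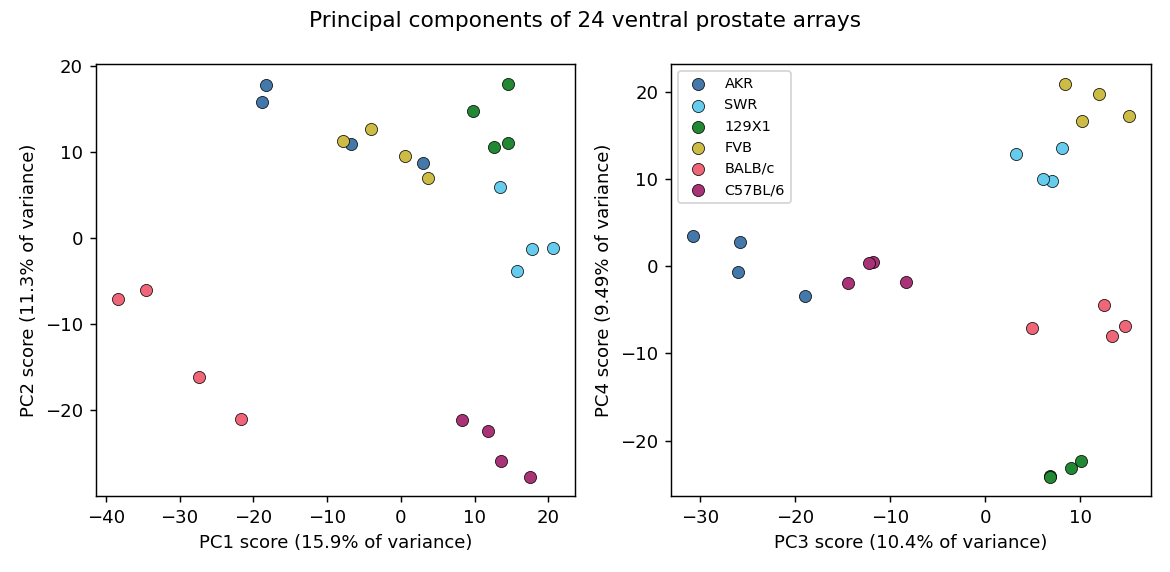
Scores of the 24 arrays on principal components 1 to 4 of the log2 values, with 1 point per array coloured by strain and the share of variance on each axis. Component 1 (15.9% of the variance) placed BALB/c at its negative end, and component 4 (9.49%) placed FVB and 129X1 at opposite ends.

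The 20 genes with the widest ranges over the 6 strains spanned 9.17-fold to 47.4-fold, and folds against strains near the bottom of the scale depend on the pseudocount. BC018473 had a log2 mean of 9.70 ± 0.17 in 129X1 and 4.13 to 4.23 in the other 5 strains, a 47.4-fold range. H2-Q10, a class I histocompatibility gene, ranged 36.0-fold, from 4.52 ± 0.38 in FVB and 4.61 ± 0.17 in SWR to 9.69 ± 0.06 in 129X1, with 9.44 ± 0.41 in AKR. Tac1, the precursor of the neuropeptide substance P, ranged 26.7-fold, from 5.70 ± 0.22 in AKR and 6.50 ± 0.34 in C57BL/6 to 10.44 ± 0.12 in BALB/c. Scgb2b27, a secretoglobin, ranged 23.2-fold, from 6.19 ± 0.37 in C57BL/6 to 10.73 ± 0.51 in FVB. The sialyltransferase St6galnac2 was at 8.43 ± 0.20 in 129X1 and at 4.19 to 4.34 in the other 5 strains, near the bottom of the scale, where their order cannot be read. Psca, a surface antigen of the prostate epithelium, ranged 16.9-fold, from 4.64 ± 0.04 in C57BL/6 and 4.76 ± 0.28 in BALB/c to 8.72 ± 0.42 in 129X1.

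The remaining 14 of the 20 genes with the widest ranges fell between 9.17-fold and 16.1-fold. Gdpd3 (15.4-fold) was high in 129X1 at 9.50 ± 0.19 and in FVB at 9.21 ± 0.19, and between 5.55 and 6.14 in the other 4 strains. The detoxifying enzyme Mgst1 (12.1-fold) was between 10.50 and 10.82 in SWR, 129X1 and FVB and between 7.22 and 7.99 in AKR, BALB/c and C57BL/6. Gpx3, an extracellular glutathione peroxidase, ranged 11.4-fold from 9.12 ± 0.17 in C57BL/6 to 12.63 ± 0.35 in BALB/c. The others were Fcgbp, Adi1, Car3, Malat1, Clu, Kcnk3, Nupr1, Hspa1b, Rps9, Adipoq and Rpgrip1. The adipocyte genes Car3 and Adipoq varied most within FVB, where their SDs were 1.91 and 1.60. With the adipocyte score of each array as a covariate, Car3 was no longer called (adjusted p = 0.41).

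In the moderated F test of limma, 5739 of 15775 probe sets (36.4%) differed among the strains at an adjusted p under 0.05. Of these, 1434 had a range of at least 2-fold and 190 of at least 4-fold, and those with a single gene symbol covered 3970 genes. The highest strain mean was most often that of BALB/c (1180) or 129X1 (1117) and least often that of FVB (700). A probe set was called strain-distinct when a strain differed from each of the other 5 in the same direction and by at least 2-fold from their mean. This held for 348 probe sets, but the number was 198 with a pseudocount of 64 and 205 with the smooth muscle score as a covariate.

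AKR ventral prostate had high heat shock transcripts, a list call lost with an estimated correlation (adjusted p = 0.24). Hspa1b and Hspa1a, both encoding inducible Hsp70 chaperones, were 6.82-fold and 5.88-fold higher than in the other 5 strains, at 11.13 ± 0.89 against 8.37 and 8.67 ± 1.25 against 6.12. Mme, a membrane peptidase that cleaves neuropeptides, was 4.27-fold higher, at 10.48 ± 0.07 against strain means from 6.65 to 9.74. At its other probe set, the one used for FVB below, the AKR arrays (10.695 to 11.142) overlapped those of BALB/c (10.741 to 11.037). The sialyltransferases St6galnac4 and St6galnac6 were 3.89-fold and 2.73-fold higher. Apof, an apolipoprotein, was 3.10-fold higher. Tac1 was 9.43-fold lower at 5.70 ± 0.22 against 8.94, but it was also low in C57BL/6 at 6.50 ± 0.34.

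Other transcripts lower in AKR were Galnt2, an enzyme that starts O-glycosylation (2.76-fold), the protein unfoldase Vcp (2.76-fold) and the 14-3-3 protein Ywhaq (2.57-fold). The class I genes H2-D1 and H2-K1 were 5.28-fold and 4.90-fold lower at their brightest strain-distinct probe sets. Of the 8 H2-D1 probe sets 5 were lower, 1 was higher and 2 were not called, and of the 4 for H2-K1 3 were lower. Another probe set of Galnt2, of Vcp and of Ywhaq was not called.

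By gene list, 9 of 14 heat shock genes were higher in AKR (10 adjusted over the list alone), among them the co-chaperones Dnaja1 (1.76-fold) and Dnajb1 (1.61-fold). The camera test of limma gave an adjusted p of 2.7e-06, and the adjusted p was 0.24 with an estimated correlation. The heat shock score of the 4 AKR arrays varied from 0.09 to 0.99. Of 19 proliferation genes 8 were higher (9 adjusted over the list alone), among them Cdk1, the kinase that drives mitosis (1.73-fold), and Rrm1, a ribonucleotide reductase subunit (1.35-fold, another probe set not called). Camera gave an adjusted p of 9e-06, and 0.064 with an estimated correlation. Of 15 fibroblast and extracellular matrix genes 7 were lower (8 adjusted over the list alone), among them the matrix proteins Postn (1.76-fold) and Dcn (1.63-fold), with an adjusted p of 6.5e-05, and 0.24 with an estimated correlation.

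Smaller list differences in AKR were higher interferon response genes (2 of 20 higher, 6 adjusted over the list alone; adjusted p = 0.0075, or 0.49 with an estimated correlation), a call lost without AKR replicate 2 (adjusted p = 0.097). Adipocyte genes were lower (1 of 9, 4 adjusted over the list alone; adjusted p = 0.013, or 0.51 with an estimated correlation), as were complement genes (2 of 9, 3 adjusted over the list alone; adjusted p = 0.015, or 0.16 with an estimated correlation). Among ribosomal protein genes 3 of 18 were lower (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.015, or 0.60 with an estimated correlation), a call lost without AKR replicate 1 (adjusted p = 0.079) and under quantile normalization (0.43). With the adipocyte score as a covariate the adjusted p was 0.96 for the adipocyte list and 0.056 for complement.

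In total, 1545 probe sets separated AKR from the mean of the other strains (737 higher, 808 lower), 119 by at least 2-fold, and 53 were strain-distinct (27 higher, 26 lower). The total was 953 without AKR replicate 3, 920 without AKR replicate 4, 870 with the adipocyte score as a covariate and 402 when the other 20 arrays were treated as 1 group.

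SWR ventral prostate had low interferon-induced transcripts, although this list call was lost with an estimated correlation (adjusted p = 0.24). Clca1, a secreted protein of mucous epithelia, was 3.79-fold higher at 6.53 ± 0.16 against 4.61. S1pr3, a receptor for sphingosine 1-phosphate, was 2.81-fold higher. The ubiquitin ligase Fbxo32 and the secretory-cell transcription factor Bhlha15 were each 2.35-fold higher, Gga1, an adaptor for sorting at the Golgi, 2.31-fold, and Creg1 2.28-fold, although a further Creg1 probe set was not called. Nupr1, a stress-induced nuclear protein, was 4.42-fold lower at 8.08 ± 0.26 against 10.22.

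The other transcripts lowest in SWR were Btg2, an antiproliferative gene (3.88-fold), the glycosyltransferase B4galnt2 (3.83-fold), the methionine salvage enzyme Adi1 (3.47-fold), Dmac2l (3.34-fold) and the RNA polymerase subunit Polr1c (2.96-fold). Other probe sets of Btg2, Adi1 and Polr1c were not called.

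Of 20 interferon response genes 11 were lower in SWR (12 adjusted over the list alone), among them the transcription factor Irf7 (2.16-fold) and the antiviral genes Rsad2 (2.05-fold) and Ifit1 (2.02-fold). Camera gave an adjusted p of 5.6e-07, and 0.24 with an estimated correlation. Of 8 basal epithelium genes 5 were higher (6 adjusted over the list alone), among them the keratin Krt15 (1.75-fold), with an adjusted p of 0.00038, and 0.072 with an estimated correlation. Smooth muscle genes were higher (5 higher and 1 lower of 12; 8 and 2 adjusted over the list alone), among them the actin Actg2 (1.58-fold), with an adjusted p of 0.0035, or 0.49 with an estimated correlation. This call was lost without SWR replicate 4 (adjusted p = 0.098), the array with the highest smooth muscle score of the strain (0.66, others −0.01 to 0.13) and with a skeletal muscle score of 1.10 (others −0.39 to −0.10). Mitochondrial respiration genes were lower (5 lower and 1 higher of 28, with the same numbers adjusted over the list alone; adjusted p = 0.019, or 0.51 with an estimated correlation), a call lost without SWR replicate 3 (0.066) and with the adipocyte score as a covariate (0.051).

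In total, 1666 probe sets separated SWR from the other strains (871 higher, 795 lower), 120 by at least 2-fold, and 36 were strain-distinct (17 higher, 19 lower). The total was 1039 without SWR replicate 1, 925 without SWR replicate 2 and 327 when the other 20 arrays were treated as 1 group.

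129X1 ventral prostate had 2 transcripts that were near the bottom of the scale in all other strains. BC018473 had an intensity of 819 ± 97.3 against 2.11, and the sialyltransferase St6galnac2 331 ± 45.7 against 3.45, which were 46.0-fold and 17.8-fold differences with the pseudocount of 16. Psca was 6.67-fold higher, B4galnt2 3.59-fold, the chromatin remodelling subunit Smarcd3 3.19-fold and the biliverdin reductase Blvrb 2.94-fold. The peptide-processing enzyme Pam, from the list of genes with reported strain differences, was 2.56-fold higher.

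The proteasome subunit Psmd6 was 6.35-fold lower in 129X1, with a further probe set not called, and Serinc3 was 5.57-fold lower with all 5 of its probe sets called. Pkig, an inhibitor of protein kinase A, was 4.64-fold lower and the sugar-cleaving enzyme Treh 4.03-fold lower. The metal-binding metallothioneins Mt1 and Mt2 were 4.52-fold and 3.46-fold lower, although a further probe set of Mt1 was not called.

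Genes of protein folding in the endoplasmic reticulum were low in 129X1, where 15 of the 26 unfolded protein response and secretion genes were lower (16 adjusted over the list alone) and none was higher, a call lost with an estimated correlation (adjusted p = 0.16). Pdia4 and Pdia6, which form disulfide bonds, were 2.22-fold and 2.09-fold lower at 7.13 ± 0.35 against 8.28 and 10.03 ± 0.15 against 11.09, with a further probe set of each not called, and Edem1, which directs misfolded glycoproteins to degradation, was 2.11-fold lower. With the preset correlation the adjusted p was 3.1e-10. Interferon response genes were higher (9 of 20, 10 adjusted over the list alone), among them Irf7 (2.26-fold) and Rsad2 (2.04-fold), with an adjusted p of 8.5e-05, or 0.35 with an estimated correlation. The interferon scores of 129X1 replicates 1 to 4 were 0.62, 0.19, 0.54 and −0.11, and that of replicate 4 lay below the −0.06 of the other strains. Class I histocompatibility genes were higher (4 of 8, 5 adjusted over the list alone), among them H2-Q10 (9.95-fold) and H2-K1 (2.41-fold, all 4 probe sets called), with an adjusted p of 0.001, or 0.072 with an estimated correlation. That call was lost when probe sets were averaged per gene (0.082). Class II genes were higher (3 higher and 1 lower of 9; 5 and 1 adjusted over the list alone; adjusted p = 0.013, or 0.24 with an estimated correlation), among them H2-Aa (2.32-fold, another probe set not called).

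Stromal and basal genes were also higher in 129X1. The calls covered smooth muscle (4 of 12 higher, 10 adjusted over the list alone; adjusted p = 0.00019, or 0.39 with an estimated correlation), with the myosin light chain Myl9 1.46-fold higher, and fibroblast and extracellular matrix genes (3 of 15, 5 adjusted over the list alone; adjusted p = 0.0035, or 0.39 with an estimated correlation). Basal epithelium genes were higher too (3 of 8, 4 adjusted over the list alone; adjusted p = 0.013, or 0.24 with an estimated correlation), with Krt15 2.31-fold higher. Immediate early genes were higher (3 of 18, 6 adjusted over the list alone; adjusted p = 0.022, or 0.39 with an estimated correlation), a call lost without 129X1 replicate 3 (0.066) or 4 (0.076).

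Secretory and cholesterol lists were lower in 129X1. Ventral prostate secretions were lower (2 of 10; 3 lower and 1 higher adjusted over the list alone; adjusted p = 0.046, or 0.28 with an estimated correlation), among them Agr2, a disulfide isomerase of secretory cells (2.54-fold). Dorsolateral and anterior prostate secretions were lower (2 of 6, with the same number adjusted over the list alone; adjusted p = 0.035, or 0.24 with an estimated correlation), as were cholesterol synthesis genes (4 of 13, 6 adjusted over the list alone; adjusted p = 0.0079, or 0.27 with an estimated correlation). Without 129X1 replicate 4 the adjusted p was 0.15, 0.087 and 0.092 for these 3 lists, and that array had the highest skeletal muscle score of all 24 (1.61, other 129X1 arrays −0.09 to 0.02). The ventral prostate call was also lost under quantile normalization (0.31), with the adipocyte score as a covariate (0.051), with averaged probe sets (0.076) and without AKR replicate 2 (0.056), AKR replicate 4 (0.050), FVB replicate 1 (0.052), BALB/c replicate 1 (0.051) or BALB/c replicate 3 (0.052). Ribosomal protein genes were lower (2 of 18, with the same number adjusted over the list alone; adjusted p = 0.012, or 0.59 with an estimated correlation), a call lost without 129X1 replicate 1 (0.15) and under quantile normalization (0.85).

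In total, 1837 probe sets separated 129X1 from the other strains (1006 higher, 831 lower), 165 by at least 2-fold, and 77 were strain-distinct (37 higher, 40 lower). The total was 738 with the smooth muscle score as a covariate and 643 when the other 20 arrays were treated as 1 group.

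FVB ventral prostate had high clusterin and, in 3 of its 4 arrays, high adipocyte transcripts, the latter a list call lost with an estimated correlation (adjusted p = 0.24). Clu, a secreted chaperone abundant in the prostate, was 6.89-fold higher at 12.51 ± 0.26 against 9.72, and all 4 of its probe sets were called. Tph1, which makes serotonin, was 4.79-fold higher, the deubiquitinase Otub1 3.59-fold (another probe set not called), the prostaglandin D receptor Ptgdr 3.10-fold, the acid phosphatase Acp5 3.05-fold and the globin Hbb-b2 2.86-fold. The peptidase Mme was 4.41-fold lower and Acaa2, a thiolase of mitochondrial fatty acid oxidation, 5.07-fold lower, with a further Acaa2 probe set not called.

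Malat1, a nuclear noncoding RNA, was 10.4-fold lower in FVB at 6.87 ± 0.38 against 10.24, but the other 4 probe sets of Malat1 were not called. Tpd52l1 was 2.70-fold lower, Spg21 2.49-fold and the imprinted transcription factor Plagl1 2.29-fold. Spg21 was not called with the smooth muscle score as a covariate (adjusted p = 0.051), although its log2 difference was −1.4 in place of −1.32.

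Of 12 smooth muscle genes 9 were higher in FVB (10 adjusted over the list alone), among them the myosin heavy chain Myh11 (1.63-fold) and the myosin kinase Mylk (1.38-fold), each with another probe set not called. Camera gave an adjusted p of 2.1e-07, and 0.24 with an estimated correlation. Of 9 adipocyte genes 4 were higher (9 adjusted over the list alone), among them the hormone Adipoq (4.20-fold, 7.67 ± 1.60 against 5.60) and the lipase Lpl (2.44-fold), with an adjusted p of 2.3e-06, or 0.24 with an estimated correlation. The adipocyte score was −0.31 in FVB replicate 1 and 1.30, 1.04 and 1.59 in replicates 2 to 4. With that score as a covariate neither Myh11 (0.11) nor Mylk (0.094) was called. Their log2 differences hardly changed, at 0.688 in place of 0.703 and 0.475 in place of 0.463, so the lost calls do not show that fat accounts for them.

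Interferon response genes were lower in FVB (6 of 20, 7 adjusted over the list alone), among them Rsad2 (1.76-fold) and the RNA sensor Ifih1 (1.59-fold), with an adjusted p of 7e-05, or 0.35 with an estimated correlation. Cholesterol synthesis genes were lower (2 of 13, 5 adjusted over the list alone; adjusted p = 0.0035, or 0.24 with an estimated correlation), as were class II histocompatibility genes (1 of 9, 2 adjusted over the list alone; adjusted p = 0.048, or 0.37 with an estimated correlation). The fibroblast and extracellular matrix list had a positive mean difference (adjusted p = 0.042, or 0.51 with an estimated correlation) although none of its 15 genes was called higher and the collagen Col6a3 was 2.28-fold lower. Adjusted over the list alone, 9 were higher and 1 lower. This call turned to a lower one short of the threshold with the adipocyte score as a covariate (0.96), and was lost without FVB replicate 4 (0.34) and without AKR replicate 3, 129X1 replicate 1, BALB/c replicate 2 or 3 or C57BL/6 replicate 2 (0.051 to 0.052). The class II call was lost with the same covariate (0.090), without FVB replicate 1 (0.091) or FVB replicate 2 (0.16) and without AKR replicate 3 or 4, SWR replicate 3, 129X1 replicate 4, BALB/c replicate 2, 3 or 4 or C57BL/6 replicate 2 or 4 (0.050 to 0.066).

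In total, 1119 probe sets separated FVB from the other strains (544 higher, 575 lower), 112 by at least 2-fold, and 35 were strain-distinct (20 higher, 15 lower). The total was 720, 663 and 698 without FVB replicates 1, 3 and 4, 356 with the adipocyte score and 218 with the smooth muscle score as a covariate, and 177 when the other 20 arrays were treated as 1 group.

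BALB/c ventral prostate had high secretory and low smooth muscle and basal transcripts by list calls that were all lost with an estimated correlation (adjusted p = 0.064, 0.24 and 0.12). Fcgbp, a mucus protein, was 7.66-fold higher at 9.28 ± 1.52 against 6.34, Car2, a carbonic anhydrase, 6.79-fold at 9.97 ± 0.64 against 7.20, and the class II gene H2-Ea 6.36-fold at 7.58 ± 0.35 against 4.91. Cfap298, a gene for the assembly of cilia (5.68-fold, another probe set not called), and the membrane-binding Anxa13 (5.41-fold) were also higher. H2-D1 was 15.8-fold higher at its brightest strain-distinct probe set, but only 3 of its 8 probe sets were higher and 4 were lower.

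Phgdh, which starts serine synthesis, was 8.20-fold lower in BALB/c at 6.79 ± 0.19 against 9.83, while 1 of the other 3 probe sets of the gene was higher and 2 were not called. Pdxdc1 was 6.59-fold lower with 3 of 4 probe sets lower and 1 higher. The potassium channel Kcnk3 was 6.55-fold lower, Coro2a 5.25-fold, Tsc22d1 4.09-fold (4 of 5 probe sets lower) and Id4, an inhibitor of transcription factors, 4.03-fold.

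Of 10 ventral prostate secretion genes 7 were higher in BALB/c and 1 lower (the same numbers adjusted over the list alone). The immunoglobulin transporter Pigr was 3.54-fold higher at 12.44 ± 0.08 against 10.61, the androgen-dependent secretory protein Pbsn 2.61-fold at 12.92 ± 0.19 against 11.54, and Msmb 2.30-fold at 13.55 ± 0.13 against 12.35, while the secreted glycoprotein Azgp1 was 2.76-fold lower. Camera gave an adjusted p of 6.5e-05, and 0.064 with an estimated correlation. Of 26 unfolded protein response and secretion genes 14 were higher and 1 lower (14 and 2 adjusted over the list alone). Pdia4 was 2.20-fold higher (another probe set not called), Creld2 2.01-fold and the chaperone Hsp90b1 1.72-fold, and Herpud1, which acts in the degradation of misfolded proteins, was 1.68-fold lower, a call lost without BALB/c replicate 2 (adjusted p = 0.082). The adjusted p of the list was 2.3e-06, and 0.26 with an estimated correlation.

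Of 12 smooth muscle genes 8 were lower in BALB/c (9 adjusted over the list alone), among them Myh11 (2.69-fold, 7.89 ± 0.08 against 9.32, another probe set not called) and the actin-binding Cnn1 (2.06-fold). The adjusted p was 2.5e-08, and 0.24 with an estimated correlation. Of 8 basal epithelium genes 6 were lower (with the same number adjusted over the list alone), among them Krt15 (2.13-fold) and the basal cell transcription factor Trp63 (1.49-fold), with an adjusted p of 0.0015, or 0.12 with an estimated correlation. Adipocyte genes were higher in 5 and lower in 1 of 9, and the list was not called (adjusted p = 0.053). The adipocyte scores of BALB/c replicates 1 to 4 were 1.44, −0.14, 0.40 and 1.08.

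Ribosomal protein genes were higher in BALB/c (12 higher and 1 lower of 18, with the same numbers adjusted over the list alone), among them Rpl27a (3.40-fold), with an adjusted p of 6.5e-05, or 0.43 with an estimated correlation. Mitochondrial respiration genes were higher (9 higher and 1 lower of 28; 10 and 1 adjusted over the list alone; adjusted p = 0.0066, or 0.48 with an estimated correlation). Under quantile normalization the ribosomal list turned to a lower one short of the threshold (0.31) and the mitochondrial call was lost (0.17).

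In total, 2985 probe sets separated BALB/c from the other strains (1310 higher, 1675 lower), 212 by at least 2-fold, and 102 were strain-distinct (48 higher, 54 lower). These were the largest numbers of the 6 strains, but not under every setting. The total was 1700 with the adipocyte score as a covariate, below 1844 in 129X1, 397 with the smooth muscle score as a covariate, above only the 218 of FVB, and 1545 when the other 20 arrays were treated as 1 group. With array weights it was 2155, below 2457 in SWR, 2300 in 129X1 and 2167 in C57BL/6. The strain-distinct number was 57 with a pseudocount of 64 and 38 with the smooth muscle score, below 39 in AKR, 39 in 129X1 and 55 in C57BL/6. Without the rescaling to a common trimmed mean, the share of BALB/c calls that were higher was 22.2% in place of 43.9%.

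The genes lowest in C57BL/6 ventral prostate included 3 glutathione-dependent enzymes, although most genes of that list were not called. Gsta4, a glutathione transferase for lipid aldehydes, was 5.52-fold lower at 5.54 ± 0.40 against 8.00, Mgst1 5.19-fold at 7.22 ± 0.24 against 9.60, and Gpx3 4.70-fold at 9.12 ± 0.17 against 11.36. The largest difference was in Tmem87a, which was 8.37-fold lower at 4.78 ± 0.44 against 7.84. Krt4, a keratin of stratified epithelia, was 5.38-fold lower, and Ccnd2, a cyclin of the G1 phase, was 4.50-fold lower with all 7 of its probe sets called.

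Adi1 was 6.42-fold higher in C57BL/6 at 10.51 ± 0.15 against 7.83, with all 3 probe sets called. The kinase Stk25 was 4.39-fold higher and the nuclease Dnase1l2 4.22-fold higher. The ribosomal protein gene Rps9 was 7.57-fold higher at 8.49 ± 0.24 against 5.57, but its other 2 probe sets were not called. Rpgrip1, a protein of the photoreceptor cilium, was 6.16-fold higher with another probe set not called, and Uqcr10, a subunit of respiratory complex III, 4.55-fold higher with 2 of its 3 probe sets higher and 1 lower.

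Of 24 glutathione S-transferases and glutathione enzymes 6 were lower in C57BL/6 and 1 higher (6 and 2 adjusted over the list alone), including Gclm, a subunit of the enzyme that starts glutathione synthesis (1.40-fold lower). The median difference of the list was −0.06 and its mean −0.32. The adjusted p was 0.048, and 0.24 with an estimated correlation, and the call was lost with the replicate number in the model (0.054), with averaged probe sets (0.087), without C57BL/6 replicate 2 (0.077) or 4 (0.057) and without AKR replicate 1, 2 or 3, SWR replicate 2 or 3, 129X1 replicate 2, 3 or 4, FVB replicate 1 or 2 or BALB/c replicate 1, 3 or 4 (0.051 to 0.066). Of 8 basal epithelium genes 5 were lower (with the same number adjusted over the list alone), among them Krt14 (2.40-fold, 2 of 3 probe sets) and the hemidesmosome collagen Col17a1 (2.09-fold), with an adjusted p of 3.9e-05, or 0.064 with an estimated correlation.

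Adipocyte genes were lower in C57BL/6 (4 of 9, with the same number adjusted over the list alone; adjusted p = 0.0081, or 0.50 with an estimated correlation), with a mean score of −0.66. This call was lost with averaged probe sets (0.054) and turned to a higher one short of the threshold with the adipocyte score as a covariate (0.92). Acute phase and innate defence genes were lower (3 of 12, with the same number adjusted over the list alone; adjusted p = 0.012, or 0.24 with an estimated correlation), among them the endotoxin-binding Lbp (1.79-fold). Smooth muscle genes were lower (2 of 12, with the same number adjusted over the list alone; adjusted p = 0.016, or 0.54 with an estimated correlation), with scores of −0.08, −0.33, −0.48 and 0.06 in replicates 1 to 4, a call lost without C57BL/6 replicate 2 (0.074) or 3 (0.13) and with the adipocyte score as a covariate (0.088).

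In total, 1750 probe sets separated C57BL/6 from the other strains (891 higher, 859 lower), 164 by at least 2-fold, and 70 were strain-distinct (36 higher, 34 lower). The total was 1152 without C57BL/6 replicate 1, 1092 with the adipocyte score and 971 with the smooth muscle score as a covariate, and 605 when the other 20 arrays were treated as 1 group.

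**Figure D2:**
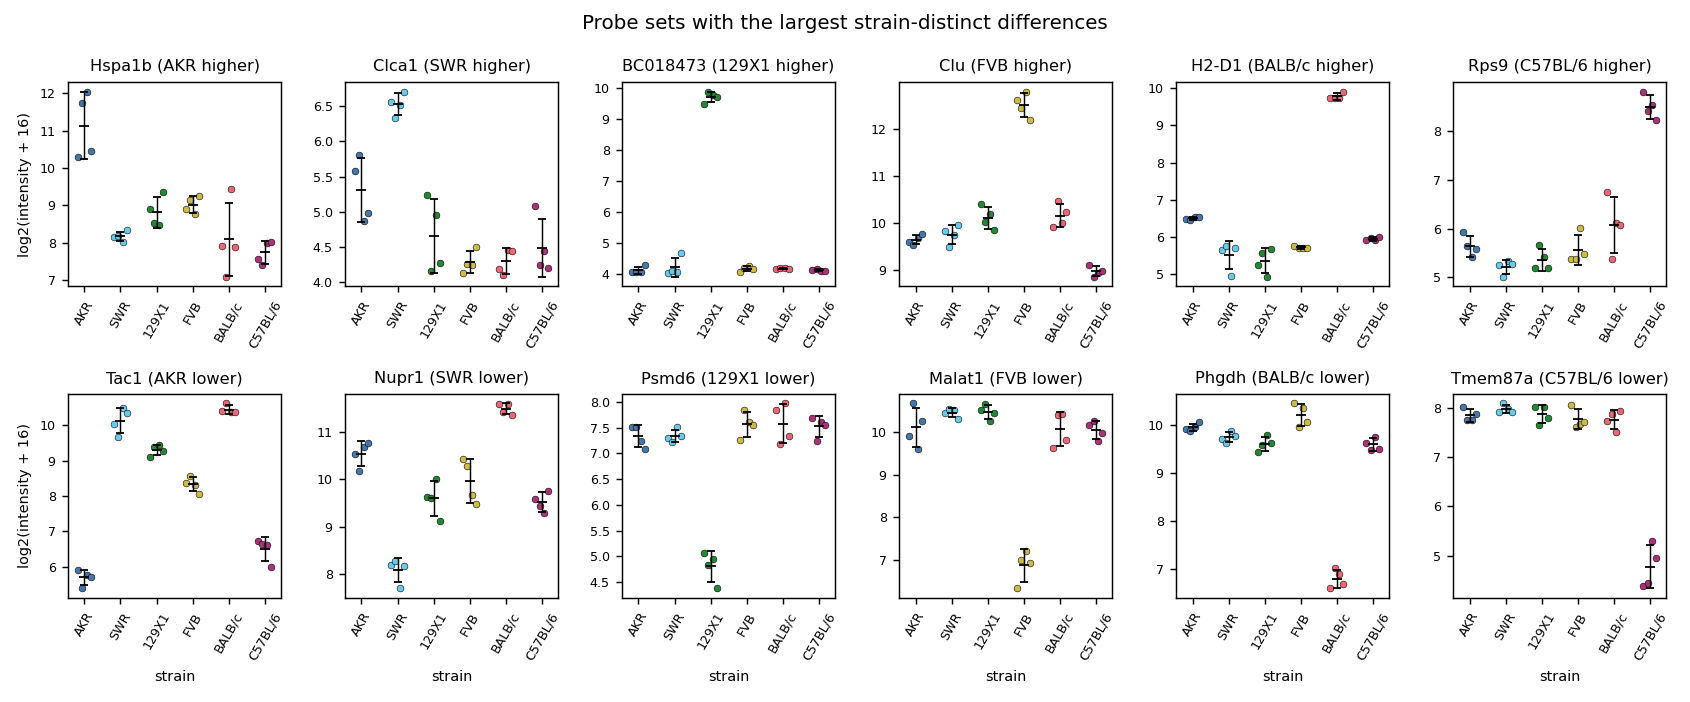
Log2 of intensity plus 16 on each array (points) with the strain mean and SD (bars), for the strain-distinct genes with the largest higher (top) and lower (bottom) difference in each strain. BC018473 was at 9.70 ± 0.17 in 129X1 and at most 4.23 on average elsewhere, and Tac1 was lowest in AKR at 5.70 ± 0.22.

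**Figure D3:**
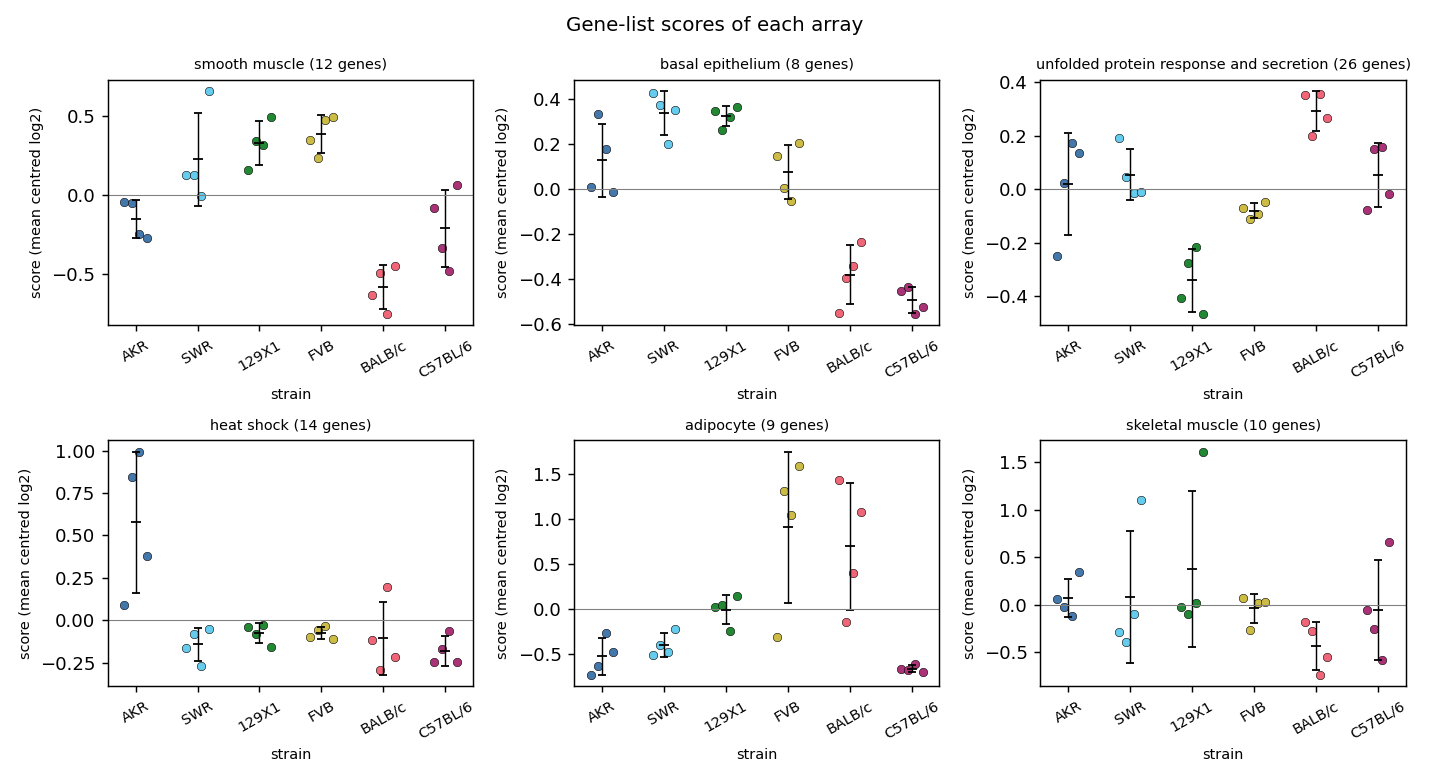
Score of 6 gene lists on each array (points; mean over the list of log2 values centred on the mean of all arrays), with the strain mean and SD (bars). The adipocyte score ranged from −0.31 to 1.59 among the 4 FVB arrays, and the heat shock score from 0.09 to 0.99 among the 4 AKR arrays.

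By probe sets called, the 5 pairs with BALB/c had the highest totals. SWR and BALB/c differed at 3117 probe sets, 129X1 and BALB/c at 2774, and BALB/c and C57BL/6 at 2305. BALB/c differed from AKR at 1992 probe sets and from FVB at 1826, close to the 1814 of AKR and C57BL/6. By probe sets differing at least 2-fold, BALB/c and FVB (307) and BALB/c and AKR (317) were below the 322 of 129X1 and C57BL/6 and the 322 of FVB and C57BL/6. Among the other settings on all arrays or on the 8 arrays of a pair, the 5 pairs stayed highest only with the 60th percentile filter and without rescaling. With only 8 arrays AKR and BALB/c had 752 against 911 for AKR and SWR, and with the smooth muscle score FVB and BALB/c had 142 against 960. The genes in which BALB/c and SWR stood at opposite ends included Nupr1 (11.49 ± 0.12 and 8.08 ± 0.26).

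The fewest probe sets, 1084, separated SWR from FVB, followed by 1171 for AKR and FVB and 1258 for SWR and C57BL/6. The SWR and FVB total was 695 without SWR replicate 1, 654 without SWR replicate 2 and 615 without FVB replicate 3, and 1748 with array weights. The remaining pairs were AKR and SWR (1583), AKR and 129X1 (1795), AKR and C57BL/6 (1814), SWR and 129X1 (1452), 129X1 and FVB (1340), 129X1 and C57BL/6 (1813), and FVB and C57BL/6 (1706). A model restricted to the 8 arrays of a pair, or with a tissue score as a covariate, moved many of these totals by over 1.5 times, down to 142 for FVB and BALB/c with the smooth muscle score.

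**Figure D4:**
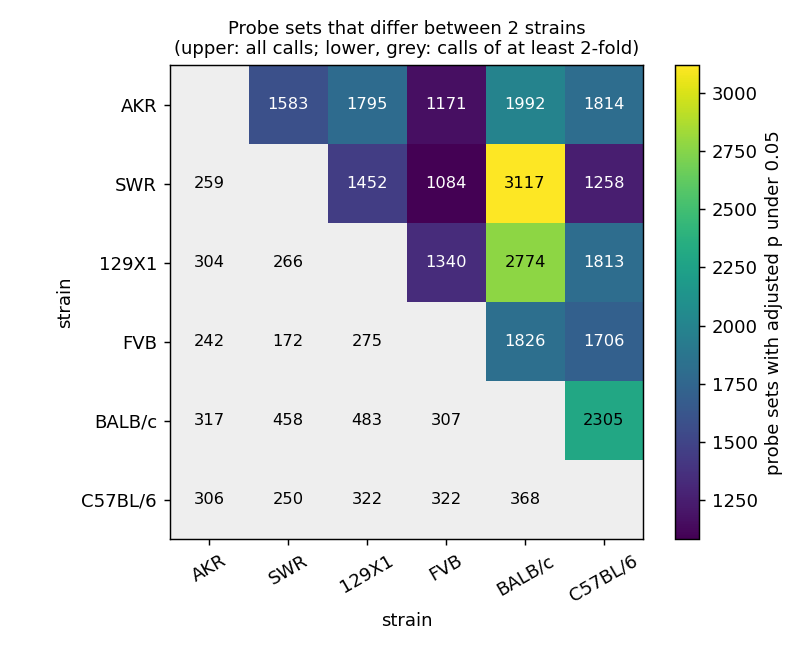
Number of probe sets called in each of the 15 pairs of strains (above the diagonal, by colour) and of those differing by at least 2-fold (below the diagonal). The numbers called ran from 1084 for SWR and FVB to 3117 for SWR and BALB/c.

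Across the 33 lists with at least 5 measured genes and the 6 strains, 40 of 198 camera tests were called, 19 higher and 21 lower. With an estimated correlation between genes 0 of the 40 calls held, while the directional test fry called 86 of the 198 tests and camera on probe sets averaged per gene called 41. Random splits of the 24 arrays gave a median of 17 and up to 34 camera calls with the preset correlation, fewer than the 40 of the real strains. No strain had a call for luminal epithelium, androgen receptor targets, steroid metabolism, endothelium, skeletal muscle, B cells and plasma cells, macrophages and dendritic cells, peripheral nerve, antimicrobial and mucosal proteins, polyamine metabolism, prostate cancer genes, fatty acid synthesis and oxidation, the circadian clock or genes with reported strain differences. The lists for seminal vesicle secretions, T and NK cells, mast cells and granulocytes, erythrocytes, urothelium, neuroendocrine cells, the interferon-inducible p200 family, kallikreins and the sex-chromosome check had fewer than 5 measured genes and were not tested.

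**Figure D5:**
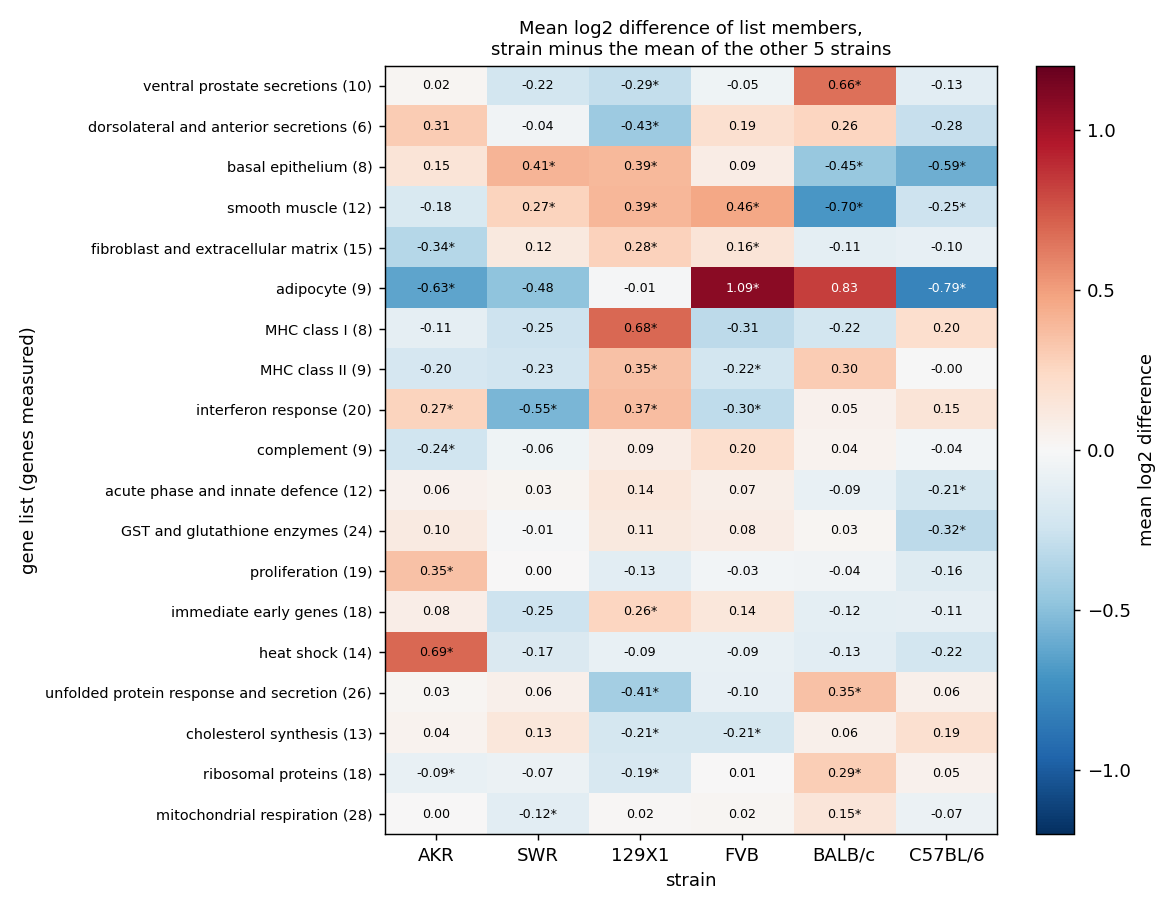
Mean log2 difference of the measured genes of each called list between a strain and the mean of the other 5 strains, by colour and number, with an asterisk at an adjusted p under 0.05 in camera with the preset correlation. None of these calls held with an estimated correlation, and the ribosomal list of BALB/c turned negative under quantile normalization.

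A few genes with reported strain differences, picked after their values were seen, gave a partial check of the strain labels. Nnt, an enzyme of the inner mitochondrial membrane whose gene carries a deletion in some C57BL/6 substrains, was lowest in C57BL/6 at 7.66 ± 0.07, against 8.29 to 8.70. Its other probe set was lower by 0.586 on the log2 scale but not called (limma adjusted p = 0.15). Glo1, which detoxifies methylglyoxal, was highest in AKR at 9.29 ± 0.21, against 8.11 to 8.41. H2-Ea was highest in BALB/c at 7.58 ± 0.35, but AKR, whose H2 haplotype is also known to carry a working copy, was at 4.93 ± 0.17, within the 4.68 to 5.21 of the other 4 strains. Whether this probe set detects the AKR form of H2-Ea was not tested, so the value does not bear on the AKR label. The innate immune sensor Naip5 was 2.80-fold higher in C57BL/6 and the heme synthesis enzyme Alad 1.92-fold lower. The Y-linked genes Uty, Kdm5d and Eif2s3y did not differ among strains (adjusted p = 0.27, 0.82 and 0.18), and Xist had means between 6.37 and 6.91 (adjusted p = 0.037).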

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

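Every test of the 3 patterns below except the share of C57BL/6 calls was chosen after the results it concerns were seen, and the BALB/c pattern was divided into parts afterwards.

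Within groups of 4 arrays, 7 of 124 groups tested held an array far from the other 3, where chance gives about 6.2. SWR replicate 4 had a Fbxo32 log2 value of 9.57, with 10.11 to 10.19 in the other SWR arrays. SWR replicate 3 had a Nupr1 value of 7.69, with 8.17 to 8.27 in the others. FVB replicate 1 had an Otub1 value of 7.34, with 6.87 to 6.91 in the others. BALB/c replicate 4 had a value of 9.91 at the named H2-D1 probe set, with 9.73 to 9.74 in the others. The fibroblast and extracellular matrix score was −0.18 in AKR replicate 2 and −0.32 to −0.31 in the other AKR arrays. The ventral prostate secretions score was −0.46 in 129X1 replicate 4 and −0.19 to −0.15 in the other 129X1 arrays. The trimmed mean was 97.4 in C57BL/6 replicate 3 and 99.6 to 100 in the other C57BL/6 arrays.

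BALB/c had the most called probe sets (2985), its smooth muscle list was lower and its ribosomal list higher. The authors' scaling is argued against as the source of the count, since under quantile normalization BALB/c still had 1.48 times as many calls as the next strain. The smooth muscle list had a camera adjusted p of 3e-09 there. Camera sets a list against the other genes, which a scale factor moves nearly alike, so this p cannot test that scaling. Fat in the samples is argued against for the smooth muscle list (camera adjusted p = 2.5e-08 with the adipocyte score as a covariate). An equal loss of all stroma is argued against by the fibroblast median of −0.17 and the endothelium median of −0.06, against −0.69 for smooth muscle. The smooth muscle minus fibroblast score was −0.49 ± 0.15 in BALB/c and 0.10 ± 0.18 in the other arrays (two-sided exact permutation test, p = 0.00019 over 10626 ways). That test treats arrays as interchangeable although they come in strains, and BALB/c was taken up because its smooth muscle list was low. Its p is therefore no measure of a difference between strains. The ribosomal difference was lost under quantile normalization (0.31) but called both with and without rescaling. Quantile normalization also changes the shape of the distribution, so this loss does not point to the authors' scaling, and the source stays open. Fat may account for part of the count, which fell to 1700 with the adipocyte score as a covariate, under the 1844 of 129X1. A difference between strains in the smooth muscle content of the gland, or in what was dissected, stays open for the count too, which was 397 with the smooth muscle score as a covariate (0.341 times the highest other strain), but both scores are partly tied to strain, the count was also not the highest with array weights (2155, 0.877 times), and the smooth muscle list had adjusted p values from 2.5e-09 to 0.24 over its alternatives, the highest with an estimated correlation (ribosomal list 5.3e-07 to 0.43).

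Adipocyte markers were higher in FVB (camera adjusted p = 2.3e-06, or 0.24 with an estimated correlation) and, short of the threshold as a list, in BALB/c (0.053). Fat dissected along with some samples may account for this. The 9 markers rose and fell together among arrays of a strain, with a mean correlation of 0.53 after strain means were removed, against −0.07 to 0.11 in 95% of 10000 random lists. The share of adipocyte transcripts thus varied among arrays of a strain. Markers of 1 cell type move together whatever the reason, so the correlation does not tell dissected fat from fat that varies between animals. A difference present in every animal of both strains stays open, since 2 of the 8 arrays had a score at or below the highest mean of the other 4 strains (−0.01, in 129X1), but this was only 1 array in each strain (−0.31 and −0.14), and both lay above the means of AKR (−0.53), SWR (−0.40) and C57BL/6 (−0.66). How much fat adheres to the gland could also differ between strains, which was not tested. The FVB count of 1119 fell to 356 with the adipocyte score as a covariate. That score is partly tied to strain, which costs calls whatever the cause, so the fall does not show that fat accounts for them.

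Strain-distinct probe sets may reflect sequence variants under the probes in place of a change in abundance. If variants were the main source, and most probes came from C57BL/6 sequence, C57BL/6 calls would be mostly higher. Lower calls would also outnumber higher ones in each other strain. The C57BL/6 share argues against this for C57BL/6 calls, at 50.9% (exact 95% interval 48.5% to 53.3%). Scaling moves this balance, but it was 52.2% to 55.9% under the other 3 scalings, which shifted the C57BL/6 median by at most 0.02. Of the calls of at least 2-fold, which shifts of that size hardly touch, 72 were higher and 92 lower. The second part was mixed. Lower calls outnumbered higher ones in AKR (808 against 737), FVB (575 against 544) and BALB/c (1675 against 1310). They did not in SWR (795 against 871) or 129X1 (831 against 1006). Only SWR kept its direction under every scaling. Without rescaling lower calls were fewer in AKR (688 against 854) and FVB (517 against 572). With median centring they were fewer in BALB/c (1375 against 1599) and more in 129X1 (948 against 856). In these strains the balance therefore cannot decide the second part. Variants as the only source are also argued against by comparisons with the other probe sets of the same genes, of which 82.8% had the same sign (exact 95% interval 79% to 86.1%). The 458 comparisons came from 208 distinct probe sets of 139 genes, and 2 distinct probe sets of a gene were compared both ways. The interval treats the comparisons as independent and is too narrow, and the repeats may raise the share. The argument is weaker in BALB/c, where the share was 67.2%, with 22 of the 37 opposite calls, against 79.8% to 96.9% in the other strains. Only 285 of the 458 were called the same way, and the median difference was 0.48 times that of the distinct probe set. A part of variants in the size of the differences therefore stays open. For the 53 of 208 distinct probe sets (25.5%) that no other probe set of the gene matched, the question stays open, since 61.9% of those in the 5 strains other than C57BL/6 were lower (26 of 42, exact 95% interval 45.6% to 76.4%). In C57BL/6 only 3 of the 11 unmatched were lower, the direction that variants under probes from C57BL/6 sequence would give, but the number is small. Malat1 in FVB, Phgdh in BALB/c and Rps9 in C57BL/6 are among the unmatched.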

How the results depend on the processing

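Models with a tissue score as a covariate and values without rescaling were added after the data were examined, as were the list runs with quantile normalization, the replicate number or an array left out. The F test total (5739) stayed between 4172 and 6108, and every strain and pair kept a total within 1.5 times under the other pseudocounts, filters, normalizations and variance model, without rescaling and with the replicate number in the model. With the replicate number 5299 of the 5739 F test calls were kept. The 72 strain differences named by the rule kept direction and call under each of those settings, with array weights, with the adipocyte score and with each array left out, except that the 60th percentile filter left 66 measured. The smooth muscle score ended the call of 1 (Spg21 in FVB, adjusted p = 0.051), without a smaller difference. At other probe sets of these genes 53 of the tests agreed, 17 missed the threshold and 17 had the opposite sign. The 51 list examples were chosen partly because their calls held, so their stability is no evidence. Of the 20 genes with the largest range, 19 kept their F test call with the adipocyte score (Car3 lost, 0.41) and all 20 under the other settings of the same probe set. Signal over background limits faint transcripts, whose folds the pseudocount compresses. The strain-distinct total was 198 with a pseudocount of 64 and 205 with the smooth muscle score, by strain 32 (AKR), 17 (SWR), 43 (129X1), 57 (BALB/c) and 42 (C57BL/6) with the pseudocount of 64, and 23 (SWR), 39 (129X1), 16 (FVB) and 38 (BALB/c) with the smooth muscle score.

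With the other 20 arrays as 1 group, whose spread then includes strain differences, the strain totals were 402 (AKR), 327 (SWR), 643 (129X1), 177 (FVB), 1545 (BALB/c) and 605 (C57BL/6). With only the 8 arrays of a pair, which leaves fewer samples, the totals were 911 (AKR and SWR), 1136 (AKR and 129X1), 711 (AKR and FVB), 752 (AKR and BALB/c), 1831 (SWR and BALB/c), 1794 (129X1 and BALB/c), 969 (FVB and BALB/c) and 1395 (BALB/c and C57BL/6). With the adipocyte score they were 870 (AKR), 356 (FVB), 1700 (BALB/c), 1092 (C57BL/6), 360 (AKR and FVB), 795 (AKR and BALB/c), 325 (SWR and FVB), 1642 (SWR and BALB/c), 538 (FVB and C57BL/6) and 904 (BALB/c and C57BL/6). With the smooth muscle score they were 738 (129X1), 218 (FVB), 397 (BALB/c), 971 (C57BL/6), 960 (AKR and SWR), 684 (AKR and 129X1), 328 (AKR and FVB), 1043 (AKR and BALB/c), 616 (SWR and BALB/c), 583 (SWR and C57BL/6), 271 (129X1 and BALB/c), 556 (129X1 and C57BL/6), 142 (FVB and BALB/c) and 414 (FVB and C57BL/6). These scores are partly tied to strain, and beyond that the cause was not tested. Array weights gave 1748 for SWR and FVB, and the cause was not tested.

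With an array left out, the F test total ranged from 5165 to 6019, and the totals that moved by over 1.5 times ranged from 920 to 1697 (AKR; 953 without AKR replicate 3 and 920 without replicate 4), 925 to 1815 (SWR; 1039 without SWR replicate 1 and 925 without replicate 2), 663 to 1157 (FVB; 720, 663 and 698 without FVB replicates 1, 3 and 4), 1152 to 1864 (C57BL/6; 1152 without C57BL/6 replicate 1) and 615 to 1163 (SWR and FVB; 695 and 654 without SWR replicates 1 and 2 and 615 without FVB replicate 3).

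Without rescaling, the share of calls that were higher moved by over 10 points in the comparisons with BALB/c, to 22.2% for BALB/c and 65.3% for 129X1 against the rest, and the median over all probe sets moved by 0.10 for 129X1 and BALB/c. With median centring it was 36.2% for AKR in place of 47.7%.

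Of the 40 list calls, 0 held with an estimated correlation, and fry made 86 calls in the 198 tests. Quantile normalization kept 35, the replicate number 39, averaged probe sets 36, fry 37, values without rescaling 40 and the adipocyte score 31. The ribosomal list in BALB/c reversed under quantile normalization (adjusted p = 0.31), and with the adipocyte score the fibroblast list in FVB (0.96) and the adipocyte list in C57BL/6 (0.92) reversed. For the adipocyte list the covariate was built from its own genes, and for the other 2 the cause was not tested. Over all alternatives the adjusted p ran from 5.3e-07 to 0.43, 0.015 to 0.96 and 0.00022 to 0.92 for these 3 lists, and from 4.5e-12 to 0.98 for the adipocyte list in FVB. With an array left out, 911 of 960 list calls held.

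Other probe sets of a gene had the opposite sign in 17 cases, and the cause was not tested. Their log2 differences were 4.324 and 0.039 (H2-D1 in AKR), 0.043 (Vcp), 0.002 (Ywhaq), 0.059 (Polr1c), −0.332, −0.761, −0.585, −0.049 and −0.425 (H2-D1 in BALB/c), 0.128, 0.397 and 0.045 (Phgdh), 2.442 (Pdxdc1), 0.12 (Tsc22d1), −0.067 (Rps9) and −0.51 (Uqcr10).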

Other observations

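Probe sets shared by several globin genes, which mark red blood cells, were highest in FVB. A probe set shared by beta-globin genes was at 12.15 ± 0.19 on the log2 scale in FVB and 11.02 ± 0.42 in BALB/c, and between 9.40 and 9.74 in the other 4 strains (FVB against the rest 2.27, limma adjusted p = 3.2e-09). The 3 probe sets shared by alpha-globin genes were higher in FVB by 4.68, 2.04 and 2.43, while the probe sets of single globin genes differed by 1.52 (Hbb-b2), 0.20 (Hba-x), −0.04 (Hba-a2) and −0.32 (Hba-a1). These probe sets were chosen after their values were seen, and blood left in the tissue was not set against a strain difference.

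Skeletal muscle genes were high in single arrays, all with the replicate number 4. The skeletal muscle score was 1.10 in SWR replicate 4, 1.61 in 129X1 replicate 4 and 0.66 in C57BL/6 replicate 4, against at most 0.35 in any other array (AKR replicate 4), but −0.55 in BALB/c replicate 4 and 0.03 in FVB replicate 4, and the list was called in no strain.

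Both tests below, of neighbouring genes and of H2 haplotypes, were chosen after related values had been seen, and the rule for gene families was changed after the pairs were seen. Strain-distinct genes lay next to each other in the chromosome order of the tested genes more often than random placement gives. Genes that were not tested were skipped, so neighbours here can have other genes between them. Among 244 distinct genes in the order of 9411 tested genes, 5 pairs of neighbours from different gene families were distinct in the same strain. For these, 10000 random placements gave a median of 1 and at most 8 (permutation p = 0.01). With gene families included there were 9 pairs (permutation p = 1e-04, the smallest these placements can give). The 5 pairs were St6galnac2 with BC018473 and Serinc3 with Pkig in 129X1, Lgr5 with Tspan8 and Trpv6 with Kel in BALB/c, and Mettl23 with Srsf2 in C57BL/6, the last in opposite directions. Shared local haplotypes may account for the 5 pairs, and overlapping transcripts were not tested as an alternative.

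Histocompatibility transcripts grouped the strains in a way that shared H2 haplotypes could give, as general knowledge, which these data do not hold, gives haplotype q to SWR and FVB and haplotype b to 129X1 and C57BL/6. Over 24 probe sets of 11 class I and class II genes, the distance between strain means was 1.85 for SWR and FVB and 2.87 for 129X1 and C57BL/6, the lowest of 15 pairs (1.85 to 10.6). Of the 45 ways to choose 2 separate pairs, 1 gave a sum as small, the predicted one (exact p = 0.022), while over the 15751 other probe sets 5 ways gave a sum as small. SWR and FVB were also the closest pair over those other probe sets (42.8), whereas 129X1 and C57BL/6 were only the tenth (48.8), so the second pair carries most of the evidence. Part of this agreement may come from probes that detect haplotypes unequally, as for H2-D1, and the result does not separate abundance from detection.

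The totals of the real strains were larger than those of every other split tried, which argues against a random assignment of arrays. Splits that mix strains carry strain differences in their spread, which lowers their counts, so the size of the gap is no measure of strain effects. Nor do the splits separate strain from anything else shared by the arrays of a strain. The real assignment of arrays to strains was the only 1 of 100 splits that gave as many calls in the F test (5739, highest other 2), in AKR (1545, highest other 62), SWR (1666, highest other 5), 129X1 (1837, highest other 3), FVB (1119, highest other 5), BALB/c (2985, highest other 259) and C57BL/6 (1750, highest other 2), and for strain-distinct probe sets (348, highest other 0). For the gene lists it was also the only 1 (40 calls), but other splits gave up to 34 and a median of 17, so that many single list calls with the preset correlation could arise without a strain difference, and 0 of them held with an estimated correlation. In each of the 15 pairs the real split was the only 1 of 35, with real and highest other totals of 1583 and 95 (AKR and SWR), 1795 and 4 (AKR and 129X1), 1171 and 10 (AKR and FVB), 1992 and 42 (AKR and BALB/c), 1814 and 10 (AKR and C57BL/6), 1452 and 1 (SWR and 129X1), 1084 and 2 (SWR and FVB), 3117 and 3 (SWR and BALB/c), 1258 and 2 (SWR and C57BL/6), 1340 and 4 (129X1 and FVB), 2774 and 6 (129X1 and BALB/c), 1813 and 1 (129X1 and C57BL/6), 1826 and 10 (FVB and BALB/c), 1706 and 1 (FVB and C57BL/6), 2305 and 3 (BALB/c and C57BL/6).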
